A study of Mus musculus with 2 samples.

How the data were processed

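H3K27ac was mapped by chromatin immunoprecipitation and sequencing in embryonic midbrain tissue from pools of 24 and 34 mouse embryos at embryonic day 14.5. The labels describe the pools as biological replicates of mixed sex, and they form 1 group of 2 samples. The deposited files are peak lists in coordinates of mm10, per the file headers and the labels: 1 list for each replicate, 1 list with no sample and 1 list of replicated peaks. Per the file headers, the list with no sample was made from the alignments of both replicates, and the replicated list from that list and the replicate lists. The aligner, the peak caller and the rule for calling a peak replicated are not given in the sources used here. The replicate lists were called per sample.

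Each peak has a signal value, which is the authors' own number for that peak and was deposited with no statement of what it is relative to. It was used to describe, rank and filter peaks within a list, and a gene's value is given as the mean and SD of its values in the lists of both replicates. Each peak also has a −log10 p and a −log10 q as deposited by the authors, with a lowest −log10 p of about 2 in every list. The summit position was also taken from the deposited lists. No list held overlapping regions, so merging them changed no count. Regions off the assembled chromosomes (9 in each replicate list, 11 in the list from both together and 9 in the replicated list) were left out of every comparison, as the gene and sequence analyses used assembled chromosomes. All region ends lay within the lengths of the GRCm38 chromosomes, the assembly that mm10 names. The number of reads is unknown, so no interval for counting error was given; the precision is limited by the number of replicates.

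Overlaps, gene annotation and motif searches were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Protein-coding genes and their transcription start sites came from GENCODE release M21, and sequence from the GRCm38 reference with its repeat masking. Coordinates are given 1-based. Random placements (100 per comparison, and fewer for the intron, intergenic and exon classes) kept each region's width and chromosome and avoided assembly gaps. A region was TSS-proximal if it touched the 1 kb on either side of a start site, and otherwise distal. A gene's start site region is the widest such region, and its signal value is the highest at its start sites in each replicate list.

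The 17 gene lists and 26 motifs, the tests, the rule for naming genes and all alternatives but those said to be chosen after seeing the data were fixed before the data were examined. Lists were tested at start sites with Fisher's exact test against all other protein-coding genes. For distal regions, the list mean was set against 10000 random lists with the same number of genes in each of 10 bins of territory, the length of genome within 100 kb whose nearest start site is the gene's. Motifs were sought on both strands of 500 bp windows at the summits of distal regions and in 1 control window each, from the same chromosome, free of regions of any list and within 2 percentage points of GC. Exact McNemar tests were used for these pairs. All families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

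Genes were named by rule: in each list the 2 marked members with the highest mean signal value and the first 2 members in list order without a replicated region; the 10 genes with the widest start site regions; the 10 with the most distal regions; and the nearest genes of the 10 distal clusters with the greatest covered length. Every motif was named, with the 3 highest and 3 lowest ratios in full. Other genes named in the text were chosen after their values were seen: Otx1, Otx2, En1, En2, Gad1, Lmx1a, Foxa1, Nr4a2, Olig2, Meis2, Pax7, Ncam1, Ptprn2, Prkca and the microRNA genes.

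The alternatives were a −log10 q of at least 2, other overlaps, start site windows of 500 bp and 2.5 kb, distance limits of 50 kb and 500 kb, GC matching of gene lists, no matching on territory, smaller windows, control windows 5 kb from the summit, the strongest regions only, other stitching gaps, and each replicate list on its own. Chosen after seeing the data were the use of only those replicated regions found in both replicate lists, start sites of all annotated genes, and motif windows with few repeats.

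The functions were tested on simulated data. With 20%, 50% and 80% of 93629 regions placed again nearby, the overlap function returned 22.2%, 51.3% and 80.6%, which includes chance overlaps. Of 100 simulated lists with 95% of genes marked, 100 were called at start sites, and 3 of 240 unchanged lists were. For distal regions the test called 31 of 100 lists with a 4-fold excess and 1 of 240 unchanged lists, so that it misses many real differences of that size. In 20000 simulated window pairs the 1 planted motif was called and none of the other 25.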

Results

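The data are maps of H3K27ac, a histone acetylation found at active promoters and enhancers, in the midbrain of mouse embryos at embryonic day 14.5. At this stage the midbrain holds both dividing neural progenitors and young neurons. The labels name 1 group with 2 biological replicates, made from pools of 24 and 34 embryos of mixed sex, so no tissues or stages were compared. The replicate 1 list held 93638 regions covering 44.4 Mb, or 1.63% of the assembled chromosomes, with a median width of 268 bp. The replicate 2 list held 86329 regions covering 45.4 Mb (1.67%), with a median width of 297 bp. A −log10 q of at least 2 was reached by 70.1% of replicate 1 regions and 79.0% of replicate 2 regions, so both lists hold lenient calls. A list from both replicates together held 102184 regions (59.6 Mb), and a replicated list held 49827 regions (46.5 Mb, 1.71%) with a median width of 645 bp. The files give no read counts, so the sequencing depth behind each region is unknown and no counting interval is given.

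Strong H3K27ac regions lay at the same places in both pools of midbrain, and weak regions often did not. Among the 10% of regions with the highest signal value, 99.99% of those in replicate 1 and 100% of those in replicate 2 were shared with the other pool. Among the weakest 10%, 24.8% and 27.2% were shared. Start site regions were shared more often (74.8% in replicate 1 and 78.1% in replicate 2) than regions away from start sites (42.7% and 44.1%).

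Over all regions, 49.9% of replicate 1 (46746 of 93629) and 52.0% of replicate 2 (44899 of 86320) were shared, where shared means an overlap of at least 50% of the shorter region. Random placement of the replicate 1 regions within their chromosomes gave a mean of 2.48% and a maximum of 2.58% in 100 placements (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Across 45258 overlapping pairs of regions, the log2 signal values of both replicates had a Pearson r of 0.814 and a Spearman rho of 0.666. This correlation is across regions, which are not independent replicates. The share depended on how much of a region had to overlap: at 80% of both regions it was 12.5% of replicate 1 and 13.6% of replicate 2. Among the 20000 strongest regions of each list it was 79.97% and 78.5%. With only regions of a −log10 q of at least 2 in both lists, it was 58.4% of replicate 1 and 54.3% of replicate 2.

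**Figure D1:**
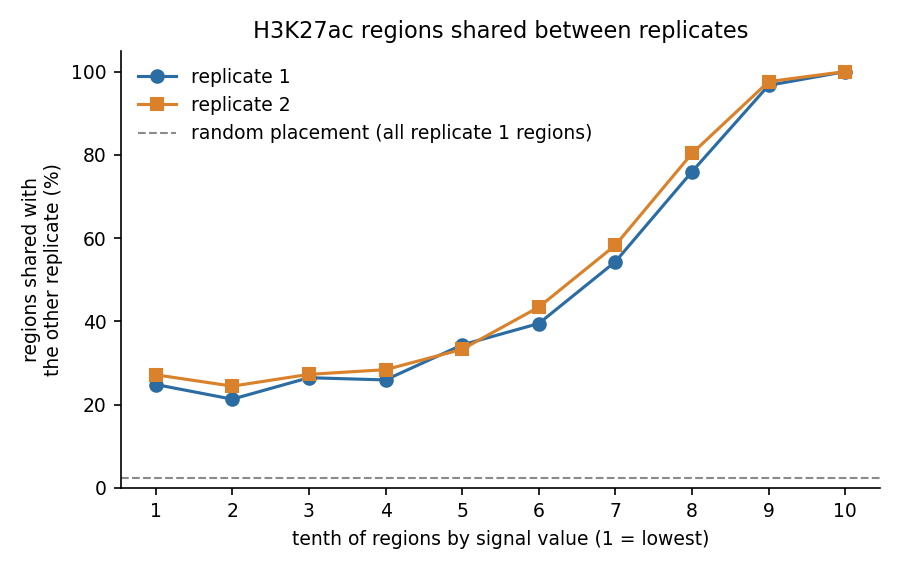
Share of H3K27ac regions of each replicate that overlapped a region of the other by at least 50% of the shorter (y axis, percent), in 10 classes of signal value with equal numbers of regions (x axis, 1 is the weakest); the dashed line is the mean for randomly placed replicate 1 regions, 2.48%. Sharing stays between 21.3% and 28.4% in the weakest 4 classes of both replicates and reaches 99.99% and 100% in the strongest.

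The replicated list was a subset of the list from both pools together: all 49827 of its regions were there with the same name and position, which is 48.8% of that list. Of its 49818 regions on assembled chromosomes, 27708 (55.6%) had at least 50% of their length overlapped by a single region in both replicate lists. For 18052 (36.2%) this held in only a single replicate list and for 4058 (8.15%) in neither. Overlaps with several regions of a replicate list were not added up. Measured against the shorter region instead, 42517 (85.3%) overlapped a region in both replicates, and every region of the pooled list that did so was in the replicated list. At 1 bp of overlap the share was 85.8%, and at 80% of the region it was 18.1%.

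The mark gathered at promoters. Of the replicated regions, 15163 (30.4%) touched the 1 kb on either side of a transcription start site of a protein-coding gene, against 5.56% of randomly placed regions. This is a 5.47-fold excess (highest of 100 placements 5.81%; one-sided permutation p = 0.0099, the smallest possible). Away from start sites, 18419 regions (37.0%) had their midpoint in an intron, 14917 (29.9%) lay between genes and 1319 (2.65%) were in exons. A smaller number of random placements gave means of 34.3%, 57.5% and 2.63% for these classes. The start site regions served 11889 of 21938 protein-coding genes (54.2%), with 12619 and 12328 genes in the lists of replicate 1 and replicate 2. In the replicate lists alone, 22.6% (replicate 1) and 23.2% (replicate 2) of regions lay at start sites.

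Promoter regions were stronger and wider than distal ones in both pools. The median signal value at start sites was 5.77 in replicate 1 and 6.18 in replicate 2, against 3.54 and 3.76 at distal regions. The ratio of medians was 1.64 ± 0.0055 (SD, n = 2). The median width was 493.5 bp and 533 bp at start sites against 245 bp and 268 bp at distal regions, a ratio of 2.00 ± 0.018 (SD, n = 2). With only 2 replicates no test between samples was made. The ratios moved to 1.34 (signal) and 1.64 (width) when the start site window was 2.5 kb, and to 1.95 and 1.78 among regions shared by both replicates.

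The widest start site region of all covered Lhx9, a LIM homeodomain gene, on mm10 chromosome 1 from 138831873 to 138849365 (17493 bp). The highest signal value at its start sites was 26.3 ± 1.19 (SD, n = 2). Next came a 16919 bp region at a start site inside Zfhx3, a zinc finger homeobox gene (chromosome 8, 108700998 to 108717916; highest signal value at the gene's start sites 68.5 ± 0.350, SD, n = 2). Regions of 14468 bp at Mn1, 13900 bp at Tnrc18, 12330 bp at Ebf3 and 11944 bp at Kdm6b, a histone demethylase gene, followed the same rule. So did a 12307 bp region at Slc32a1, which encodes the vesicular GABA transporter. A region of 12229 bp covered start sites of both Asic4 and Gmppa, and 1 of 12056 bp lay inside Tcf7l2 on chromosome 19 (55894974 to 55907029).

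Promoters of midbrain regional genes, neural progenitor genes and neuronal genes carried the mark. Most promoters of Hox genes and of blood, vessel, muscle and liver genes had no replicated region. Depth is unknown, so weak marking at these promoters cannot be excluded. Of 22 midbrain regional transcription factors and organiser signals, 20 (90.9%) had a replicated region at a start site, against 54.2% of the other genes. All 18 neural progenitor genes, all 18 pan-neuronal genes and all 15 housekeeping genes had one. For 5 of the housekeeping genes, 2 progenitor genes, 1 pan-neuronal gene and 1 midbrain gene, such a region also held a start site of another protein-coding gene. None of 19 Hox genes, which pattern the hindbrain and spinal cord, and none of 12 erythroid genes had one.

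In the midbrain list, the highest signal values were at Tcf7l2 (29.7 ± 8.50) and Lhx5 (29.2 ± 0.540; SD, n = 2 here and for the other genes). Otx2, which specifies forebrain and midbrain, had 12.9 ± 3.06, En1 21.01 ± 0.103 and En2 25.1 ± 0.436. En1 and En2 mark the midbrain and the boundary to the hindbrain. The members without a replicated region were Wnt1 and Dmbx1, although each replicate listed a weak region at Dmbx1 (3.33 in replicate 1 and 4.80 in replicate 2). Of the progenitor genes, Msi1, an RNA-binding protein gene, had 62.9 ± 5.07, and Dll1, a Notch ligand gene, 35.4 ± 4.93. Of the pan-neuronal genes, Tubb3, a neuronal tubulin, had 40.6 ± 0.373 and Myt1l 30.1 ± 3.99. Of the housekeeping genes, Actb had 76.8 ± 3.81 and Ywhaz 54.1 ± 19.0.

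Among the transmitter genes, Slc17a6, the vesicular glutamate transporter of subcortical neurons, had 35.8 ± 0.129, and the GABA genes Gad2 (28.8 ± 3.87), Slc32a1 (22.0 ± 1.85) and Gad1 (17.7 ± 3.97) were marked. Slc17a7 and Slc17a8, other glutamate transporters, and the remaining 6 of the 12 genes were not, so that 4 of 12 were marked (adjusted p = 0.195, Fisher's exact test). Dopaminergic neuron genes were marked in 6 of 13 cases (adjusted p = 0.668, Fisher's exact test). The regulators Lmx1a, Foxa1, Foxa2 and Nr4a2 were among them. Ddc had the highest value (10.2 ± 0.378), followed by Foxa2 (7.27 ± 0.874). The start site region of Ddc (chromosome 11, 11820458 to 11823229) lay inside the gene (minus strand, 11814101 to 11898144), far from its 5' end. Pitx3 and Th, the dopamine synthesis gene, had no replicated region, and each had a region in 1 replicate only. Of the telencephalic genes, 11 of 18 were marked (adjusted p = 0.681, Fisher's exact test), with Bcl11b (31.3 ± 2.36) and Lhx2 (26.1 ± 8.26) highest. Most marked members were weaker: their median signal value was 5.55, against 13.7 for the marked midbrain regional genes. Foxg1 and Emx1, 2 genes of the early forebrain, had no start site region in the list of either replicate.

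Glial and cell cycle genes were not called, although some calls depended on the setting. Oligodendrocyte lineage genes were marked in 3 of 12 cases (adjusted p = 0.110, Fisher's exact test), at Cnp (5.72 ± 0.806), Mbp (4.68 ± 1.15) and Olig2. Olig1 and Sox10 had no replicated region, although Olig1 had 1 in replicate 1 (3.66). This list was called less often marked under 4 of 7 alternatives (1 of the 4 chosen after seeing the data), with adjusted p from 0.0115 to 0.0283 (Fisher's exact test, and a permutation test for GC matching). Astrocyte genes were marked in 6 of 10 cases (adjusted p = 0.762, Fisher's exact test), led by Nfib (24.2 ± 0.604) and Slc1a2 (21.5 ± 0.189). Gfap and Aqp4 had no replicated region, but Aqp4 had a weak region in both replicate lists (3.59 and 2.91) and Gfap had 1 in replicate 1 (3.70). Cell cycle genes were marked in 11 of 14 cases (adjusted p = 0.137, Fisher's exact test), led by Ccna2 (13.1 ± 2.56) and Mcm5 (9.35 ± 2.79). Cdk1 and Aurkb had no replicated region, but Cdk1 had 1 in replicate 2 (4.12) and Aurkb in replicate 1 (3.70). From replicate 2 alone the cell cycle list was called more often marked (92.9%, adjusted p = 0.0101, Fisher's exact test).

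Markers of other cell types and organs were marked less often than other genes. The counts were 3 of 14 microglia and macrophage genes, 2 of 14 endothelial and pericyte genes, and 2 of 14 meningeal and mesenchymal genes. They were 3 of 14 liver genes and 1 of 14 heart and skeletal muscle genes. The marked members were mostly weak. C1qb had 4.85 ± 0.0645, Esam 4.44 ± 0.522, Foxc1 4.25 ± 0.182, Twist1 3.74 ± 0.0542 and Afp 5.36 ± 0.0720. The start site region of Afp (chromosome 5, 90507426 to 90507817) lay inside the gene (plus strand, 90490737 to 90508907), near its 3' end. Tmem119 and Pdgfrb had a replicated region but none in the lists of the single replicates. Without a replicated region were Aif1 and Cx3cr1 (microglia), Pecam1 and Cdh5 (endothelium), Gata1 and Klf1 (erythroid), Foxc2 and Col1a1 (mesenchyme), Alb and Apoa1 (liver), and Myod1 and Myf5 (muscle). The same held for Hoxa1 and Hoxa2. Of these, Pecam1 (3.70), Cdh5 (2.45), Klf1 (2.99), Apoa1 (2.59) and Hoxa2 (3.05) had a weak region in replicate 1. Stronger values stood at Apoh (17.8 ± 1.38), whose region also holds a start site of Prkca, and at Myh7 (14.9 ± 4.16).

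By Fisher's exact test, two-sided and with Benjamini-Hochberg adjustment over 17 lists, 4 lists were marked more often and 7 less often than other protein-coding genes. The adjusted p was 0.00101 for the midbrain list, 9.6e-05 for both the progenitor and the pan-neuronal list, and 0.000374 for the housekeeping list. For the lists marked less often it was 6.08e-06 (Hox), 0.000361 (erythroid), 0.00122 (heart and muscle), 0.00945 (endothelial, and also meningeal) and 0.0244 (microglia, and also liver). Genes are not replicates, so these tests describe the lists in this tissue. The Hox genes lie in groups on chromosomes 2, 6, 11 and 15, and some erythroid and liver genes are also neighbours. The test counted each gene as independent, so the p for these lists can be too small. The microglia and liver lists were no longer called against random lists matched on GC content (adjusted p = 0.0975 and 0.0822, permutation test), nor with a 2.5 kb window, where 42.9% and 35.7% of their genes were marked (0.513 and 0.233, Fisher's exact test). From replicate 1 alone 28.6% of endothelial, 35.7% of meningeal and 28.6% of liver genes were marked, and these lists were not called (adjusted p = 0.0555, 0.171 and 0.0555, Fisher's exact test).

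**Figure D2:**
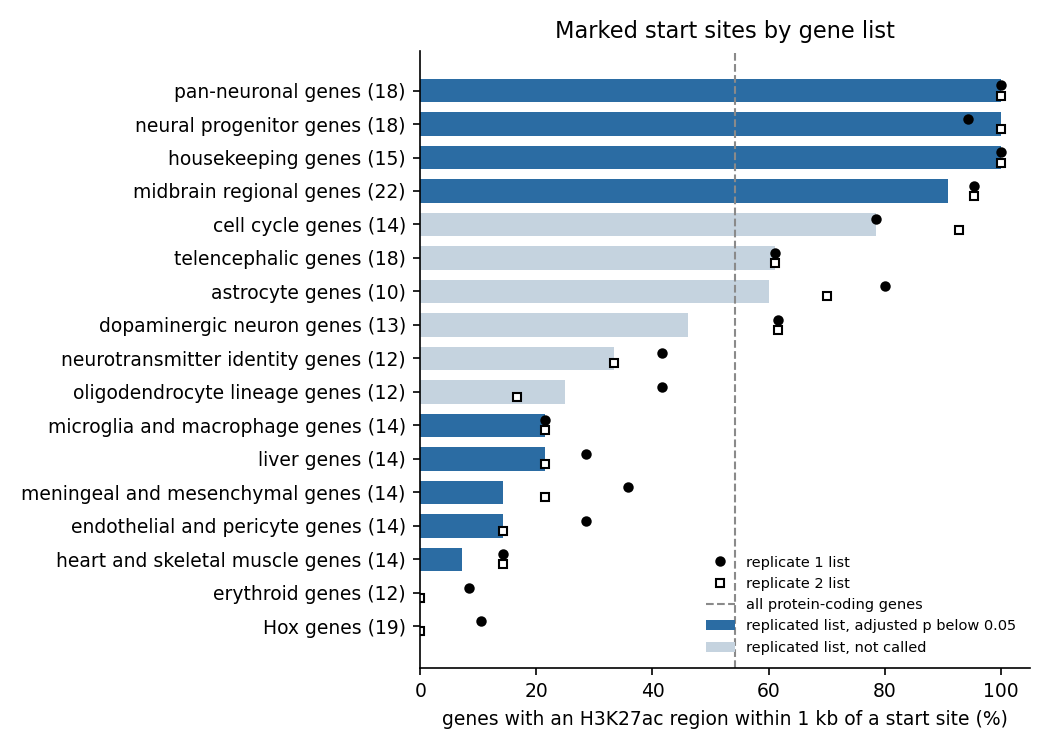
Percent of each list's genes (x axis; number of genes in parentheses) with an H3K27ac region within 1 kb of a start site: bars are the replicated list, points the list of each replicate, and the dashed line all protein-coding genes (54.2%). Dark bars have an adjusted p below 0.05 in Fisher's exact test; 4 lists stand above the line and 7 below it, and the Hox and erythroid bars are at 0.

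Midbrain regional genes and pan-neuronal genes also had many distal regions around them. Each distal region was given to the protein-coding gene with the nearest start site within 100 kb. In this way 26731 of 34655 distal regions went to 6561 genes. Midbrain regional genes had a mean of 10.8 distal regions per gene against 2.25 in random lists of genes with surroundings of like size, a 4.79-fold excess. Tcf7l2 had 44, Meis2 33 and Pax7 18. Pan-neuronal genes had 14.9 against 3.69, a 4.05-fold excess, with 51 at Myt1l, 50 at Rbfox3 and 39 at Ncam1. The adjusted p was 0.0017 for both lists (two-sided permutation test with 10000 random lists, raw p = 0.0002, the smallest they can give). The random lists were drawn from all protein-coding genes, marked at a start site or not. The excess is thus not separated from the higher share of marked genes in both lists.

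No other list passed the threshold. Astrocyte genes had 8.20 distal regions per gene against 2.34 (adjusted p = 0.0873, permutation test), neural progenitor genes 5.89 against 2.31 (0.111) and telencephalic genes 3.83 against 1.70 (0.158). Dopaminergic neuron genes had 3 against 2.37 (0.752), transmitter genes 2.25 against 1.05 (0.314) and oligodendrocyte genes 1.83 against 0.945 (0.442). Cell cycle genes had 1.21 against 0.826 and microglia genes 1.21 against 0.757. Housekeeping genes, all marked at their promoters, had 0.867 against 0.720. Meningeal genes had 0.643 against 2.51 (0.180), endothelial genes 1.43 against 2.25, heart and muscle genes 0.714 against 0.939, liver genes 0.357 against 0.957, erythroid genes 0.333 against 0.462 and Hox genes 0.211 against 0.223. Without matching on the size of the surroundings, 4 lists were called, the progenitor and astrocyte lists being added. From the list of replicate 1 or replicate 2 alone, which hold more distal regions, the mean was 20.0 and 20.2 for midbrain regional genes and 27.8 and 26.1 for pan-neuronal genes, and both calls held. With a limit of 50 kb the progenitor list was added (adjusted p = 0.0238, permutation test).

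**Figure D3:**
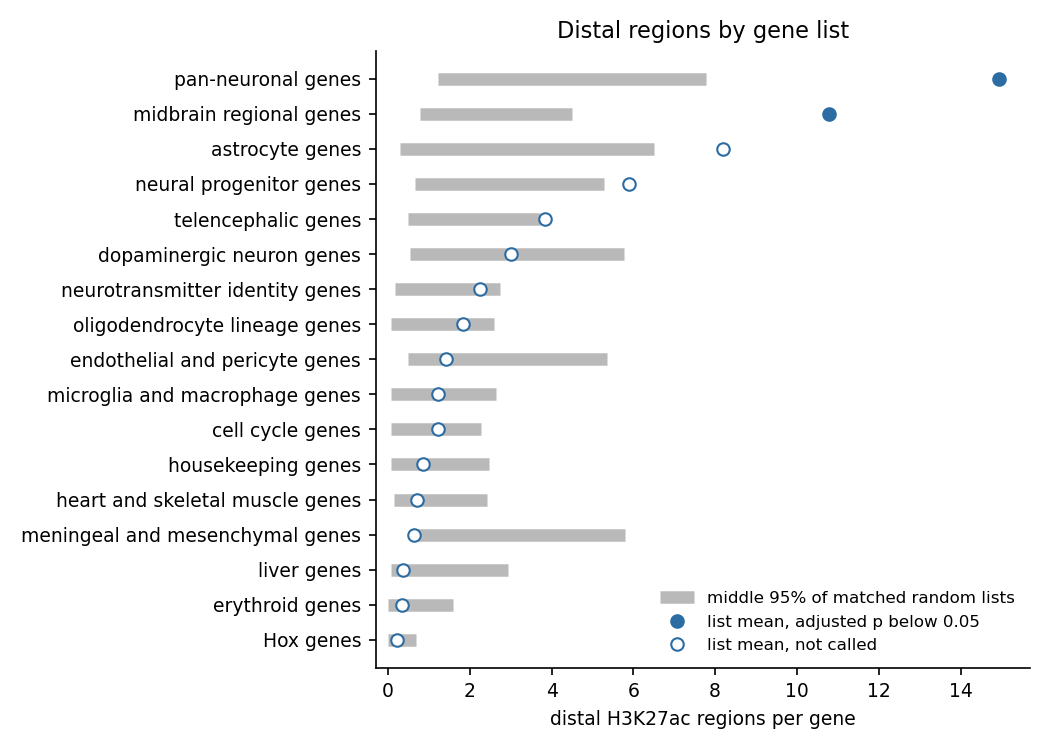
Mean number of distal H3K27ac regions per gene in each list (circles, x axis) and the middle 95% of 10000 random lists matched on the size of the genes' surroundings (grey bars). The filled circles, at 14.9 for pan-neuronal and 10.8 for midbrain regional genes, have an adjusted p below 0.05.

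Msi2, an RNA-binding protein gene, had the most distal regions of any gene (103), followed by Zmiz1 with 96 and Gse1 with 78. Rere had 56, the kinase gene Fyn 54, the RNA-binding protein gene Celf4 53, Mvb12b 52, Myt1l 51, and Ctnnbl1 and Rbfox3 50 each. Stitching distal regions over gaps of up to 10 kb gave 17531 clusters, of which 10433 were single regions and 1143 held 5 or more.

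The cluster with the greatest covered length held 143 regions (142704 bp) on mm10 chromosome 11 from 88330501 to 88651278, with its midpoint in Msi2 (88339382 to 88718513). The next had their midpoints in Zmiz1 (chromosome 14, 25445427 to 25669646; 89 regions, 85995 bp) and in Gse1 (chromosome 8, 120322474 to 120578450; 71 regions, 83796 bp). Clusters with midpoints in Celf4 (60 regions), Zfp423 (34) and Ctnnbl1 (46) were also among the top 10. A cluster of 58 regions on chromosome 12 (117150622 to 117288135) had its midpoint inside Ptprn2 and contained Mir153, and its nearest start site, of Rapgef5, was 297100 bp away. The clusters nearest to Cstad and Src had midpoints outside protein-coding gene bodies, although their spans reached the start sites of these genes (Cstad: chromosome 2, 30591098 to 30795091, 49 regions; Src: chromosome 2, 157454259 to 157553700, 32 regions). A cluster nearest to Polg also had its midpoint outside such genes; it lay on chromosome 7 (79495954 to 79549674; 10 regions covering 45433 bp) and contained Mir9-3 and its host gene Mir9-3hg. Mir9-3 encodes miR-9, a microRNA of neural tissue. Of all distal regions, 2095 (6.05%) lay within 1 kb of a start site of a gene that is not protein-coding.

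In distal regions and control windows matched on GC content, the homeodomain sequence TAATTA was found in 14.0% of distal windows against 8.23% of controls, the proneural E-box CAGCTG in 34.1% against 25.6%, and the SOX sequence AACAATG in 8.71% against 6.72%. The POU octamer ATGCAAAT was found in 4.17% against 2.61%. The HNF4 sequence of liver and gut was less frequent and the PU.1 sequence of macrophages was not called, but the MEF2 sequence, of factors that also act in muscle, was more frequent.

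The highest ratio was that of the paired RFX site (GTTGCCNNGGCAAC), with 46 of 34548 distal windows against 4 control windows (ratio 11.5, adjusted p = 1.05e-09, exact McNemar test). MEF2 (CTATTTATAG) had 68 against 20 windows (ratio 3.40, adjusted p = 6e-07, exact) and NRF1 (GCGCATGCGC) 38 against 14 (ratio 2.71, adjusted p = 0.00207, exact). The lowest ratios were those of HNF4 (CAAAGTCCA; 193 against 241 windows, ratio 0.801, adjusted p = 0.0341, exact), PU.1 (AGAGGAAGTG; 143 against 156, ratio 0.917, adjusted p = 0.504, exact) and AP-1 (TGACTCA; 2659 against 2868, ratio 0.927, adjusted p = 0.00552, exact).

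Of 26 motifs, 17 were called more frequent and 2, HNF4 and AP-1, less frequent. Besides those named above, the motifs called more frequent were the SP/KLF GC box (ratio 1.81), ZIC (1.34), the single RFX site (1.28), EBF (1.24), the GATA-TAL composite (1.21), TCF/LEF (1.205), MEIS/TGIF (1.19), TEAD (1.12), GATA (1.11) and the NEUROD/NEUROG E-box (1.06). The CTCF core, the NFI full site, the ETS core, the REST site, CREB and the OTX/PITX sequence (0.965) were not called. The regions are many, so small ratios pass the test. In 200 bp windows the paired RFX site had a ratio of 1.33 and was not called, nor were the single RFX site (1.11), SP/KLF (1.17), TEAD (1.14), HNF4 (0.787) and NRF1 (0.8), while the OTX/PITX sequence was called less frequent (0.817). Repeats covered 31.5% of the control windows and 11.9% of the distal windows; in windows with under 20% repeats on both sides, an alternative chosen after seeing the data, 13 of the 17 motifs kept their call, and EBF, GATA, TEAD and NRF1 did not. The ETS core (1.14 in all windows) was called less frequent in the windows with few repeats (0.792, adjusted p = 0.0385, exact McNemar test). The direction turned for TEAD in these windows (0.921, not called), against control windows 5 kb from the summit (0.98, not called) and among the 5000 strongest distal regions (0.702). It also turned for GATA against the windows at 5 kb (0.912), which were not matched on GC or kept free of H3K27ac regions.

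**Figure D4:**
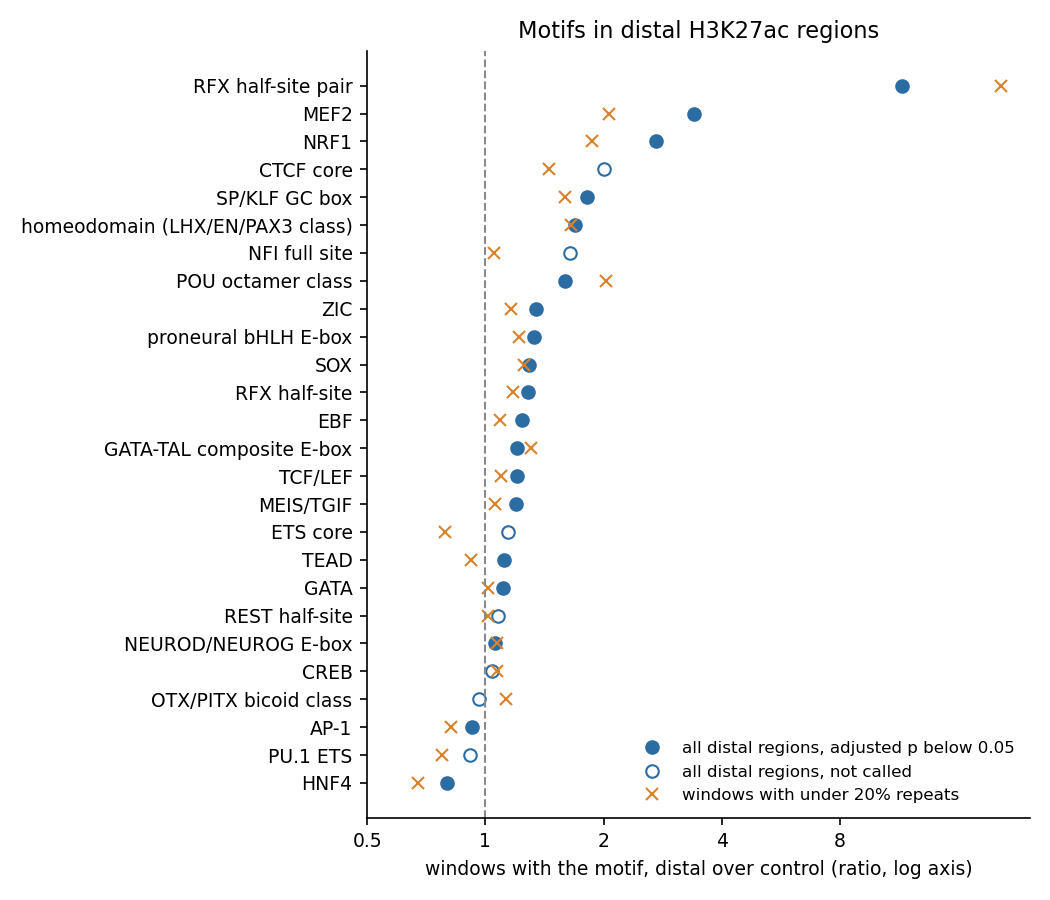
Ratio of the share of 500 bp windows with each motif in distal H3K27ac regions to that in GC-matched control windows (x axis, log scale), for all 34548 window pairs (circles, filled where the adjusted p is below 0.05) and for 28280 pairs with under 20% repeats (crosses). The homeodomain ratio is 1.70 in all pairs and 1.66 in the pairs with few repeats, and the OTX/PITX ratio is 0.965 and 1.13.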

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

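The list from both replicates together held 52355 regions on assembled chromosomes that are not in the replicated list and that the comparisons did not use. They drew attention because they form a signal in data outside those comparisons. Their median signal value was 2.98, against 4.90 in the replicated list. Of them 5470 (10.4%) lay at start sites, against a mean of 4.46% and a maximum of 4.69% in 100 random placements (permutation p = 0.0099, the smallest they can give). The replicated list also held 9 regions on sequences that are not part of an assembled chromosome, and these were not used in the comparisons either.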

How the results depend on the processing

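The ratio of the paired RFX site (11.5) was 1.33 in 200 bp windows and 20.5 in windows with few repeats; the cause was not tested. Replicate sharing (49.9% and 52.0%) was 12.5% and 13.6% at 80% reciprocal overlap, and 79.97% and 78.5% among the 20000 strongest regions. The share of replicated regions overlapped to 50% by a single region in both replicates (55.6%) was 85.8% at 1 bp and 18.1% at 80%. The changes at other overlaps follow from the stricter or looser rule. For the strongest regions sharing rises with signal value, but both lists were cut to 20000 regions. A strong region whose partner fell outside that cut therefore counted as not shared. The ratio of start site to distal medians (1.64 for signal value, 2.00 for width) was 1.34 and 1.64 with a 2.5 kb window and 1.95 and 1.78 among shared regions; the cause was not tested. The excess at start sites held under all 7 alternatives, with shares from 22.6% to 35.0%, and from 22.6% to 23.2% when a replicate was left out.

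The 4 lists called more often marked at start sites kept that call under all 7 alternatives, 1 of them chosen after seeing the data. The number of lists called less often marked ranged from 4 to 8 when a replicate was left out, and that of lists called more often from 4 to 5, the cell cycle list being added from replicate 2 alone. From replicate 1 alone 4 lists were called less often marked. The oligodendrocyte list was called less often marked with a 500 bp window, with GC matching, from replicate 2 alone and with regions in both replicate lists only. Without matching on territory 4 lists were called for distal regions, as genes with large territories were then no longer set against genes of like territory; the midbrain and pan-neuronal lists kept their call under all 6 alternatives, and no replicate left out changed the 2 calls or the count of 0 lower lists, while the means rose to 20.0 and 20.2 (midbrain) and 27.8 and 26.1 (pan-neuronal), as the replicate lists hold more distal regions. For motifs, control windows 5 kb from the summit gave 4 called less frequent, among them GATA, which reversed (ratio 0.912). These controls were not matched on GC (45.4% against 48.9%) and were not kept free of H3K27ac regions or start sites. TEAD reversed among the 5000 strongest distal regions (0.702); the cause was not tested. Leaving out a replicate gave 18 to 19 motifs called more and 1 to 2 less frequent. Of the 10 top clusters, 5 to 8 remained under other gaps or a ranking by signal. No paired analysis was possible because the samples form a single group. Depth is unknown, so weak regions absent from a list cannot be read as unmarked.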

Other observations

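Of the tests below, those of gene number on chromosome X, of repeats for the OTX/PITX motif and of the greater width of midbrain regional genes were chosen after the result was seen, as was the setting with few repeats; the other tests were written before, and only the form in which their widths are given was chosen later.

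The start site regions of pan-neuronal and neural progenitor genes were among those wider than random lists of like signal value. The median width was 3087.5 bp over the 18 marked pan-neuronal genes and 2752 bp over the 18 neural progenitor genes, against 1245 bp over all marked genes. It was 1678 bp over the 15 housekeeping genes, 947 bp over the 11 marked telencephalic genes and 570 bp over the 11 marked cell cycle genes. Random lists of marked genes with like signal values had a median of 1615.5 bp for the pan-neuronal list (upper end of their middle 95% 2037 bp) and 1188.25 bp for the progenitor list (upper end 1573.51 bp). Dopaminergic neuron genes (6 marked, 2041.5 bp against an upper end of 1265.02 bp) and astrocyte genes (6 marked, 2145 bp against 1642.02 bp) also lay above their random lists. Matched on annotated start sites instead, both lay below the upper end (2053.06 bp and 2191.01 bp). Both still passed the threshold of 0.05 there, narrowly (adjusted p = 0.0478 for each, one-sided permutation test). Without matching, the dopaminergic list lay below it (2127.51 bp) and the astrocyte list above it (2106.5 bp). Random lists of like signal value had 1743 bp for the housekeeping list, above the list's own median, and 640 bp for the cell cycle list, so that neither is unusual for its signal.

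Midbrain regional genes had the widest start site regions of the lists with at least 5 marked genes, the only lists tested. Their 20 marked members had a median of 5152 bp, with 12056 bp at Tcf7l2, 10582 bp at Lhx5 and 8615 bp at Otx2. The 4 marked transmitter genes, too few for that test, were wider still: 5486 bp at Slc17a6, 10234 bp at Gad2, 11009 bp at Gad1 and 12307 bp at Slc32a1. The median of the midbrain list was 3.04 times the upper end of the middle 95% of random lists of marked genes (one-sided permutation test, adjusted p = 0.000267, raw p = 0.0001, the smallest that 10000 lists can give). Matching the random lists on signal value left it at 3.21 times that limit, and matching on the number of annotated start sites at 3.05 times, which argues against both as the whole cause. No biological explanation was tested, as the design has 1 tissue; the widths at these genes in other regions of the embryo would show whether they are particular to midbrain.

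Distal H3K27ac was sparse on chromosome X, with 2.68 regions per Mb against 11.1 to 21.4 on the autosomes. Start site regions were also sparser, with 2.97 per Mb against 4.20 to 10.3. The share of marked genes was 39.1% against 44.3% to 66.1%, at 5.80 genes per Mb against 5.50 to 14.3. Fewer genes do not account for the sparse distal regions: there were 1.18 distal regions per gene with a start site region, against 2.10 to 4.52 on the autosomes. Nor does repeat sequence: outside repeats, which make up 46.8% of chromosome X and 30.6% to 35.8% of autosomes, there were 5.03 distal regions per Mb against 16.5 to 30.9. A candidate explanation is lower signal from the whole chromosome, as from fewer active copies in a mixed-sex pool: at start sites with at least 60% GC, unmarked genes counted as 0, the median signal value was 8.18 on chromosome X and 10.5 to 14.4 on autosomes. Among called distal regions the median signal value was not lower, at 4.74 (autosomes 4.29 to 4.38). At called start site regions it was 9.43, within the range of the autosomes (9.09 to 11.4) but below their median. Regions too weak to be called are missing from these medians, so they cannot decide whether signal was lower over the whole chromosome. In a calculation added after seeing the data, autosomal signal was scaled by the ratio of chromosome X to the autosomal median at the GC-rich start sites (0.669). Of autosomal distal regions, 49.6% would then stay above their own 5th percentile, while the density outside repeats on chromosome X was 23.8% of the autosomal median. That percentile (2.87) was not the rule that made the replicated list. Regions of the list from both replicates together that are not in the replicated list had a median signal value of 2.98. The calculation thus cannot show how much of the deficit lower signal would account for. The ratio also came from start sites with at least 60% GC, not from distal regions, so the explanation stays open. No biological explanation was tested.

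The OTX/PITX sequence TAATCC was no more frequent in distal regions than in controls (15.3% against 15.9%), although Otx2 and Otx1 were marked at their promoters. Repeats in the control windows are a candidate cause. The sequence was 1.73 times as dense in repeat-masked as in other bases of those windows (95% interval 1.65 to 1.82), and in windows with few repeats it was found in 14.9% of distal windows against 13.2% of controls. That ratio, 1.13 (adjusted p = 1.27e-08, exact McNemar test), was obtained with GC matched, as in the comparison of all windows, so GC content was not tested as a cause. No biological explanation was tested.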
